A study of Homo sapiens with 4 samples.

How the data were processed

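Enhanced crosslinking and immunoprecipitation in its single-end form (seCLIP) was used to map where PRPF39, a relative of a yeast U1 snRNP protein, touched RNA in HepG2 cells, an established human liver cancer cell line. The 4 libraries were 2 immunoprecipitated replicates and 2 size-matched inputs, which are the RNA of the same gel range without antibody selection. Per the labels' protocols, cells were crosslinked at 254 nm with 400 mJ/cm2, RNA was trimmed with RNase I for 5 min at 37 °C, and a polyclonal PRPF39 antibody was used. Per the submitters' processing notes, UMI-tools 1.0.0, cutadapt 1.14, STAR 2.7.6a and SAMtools 1.6 were among the tools and GRCh38 was the genome build. The peak caller is not given in the sources used here.

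Each replicate had a list of peak clusters, and the series had a table of peaks found in both replicates. The −log10 values in these lists are the authors' deposited −log10 p of immunoprecipitated against input reads. The log2 values are the authors' deposited log2 fold of immunoprecipitated over size-matched input. Both belong to a cluster and were used to describe, rank and filter clusters, and −log10 p stops at 400. Values in the table of both replicates are printed as the authors' values, with no SD. In the 23 regions that coincide exactly with a cluster of each replicate, the table's log2 fold was the mean of both replicates' folds and its −log10 p the smaller of both in 23 of 23, within 0.001. The replicate value of a peak is that of the cluster with the largest overlap, which need not be the cluster behind the authors' value. Read counts and depth per library were not analysed here, and depth is therefore unknown. Many clusters share a fold, and the commonest value in replicate 1 covers 15741 clusters and in replicate 2 covers 19297 clusters. The input libraries had no separate values and entered through the deposited folds.

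A cluster was called enriched at a −log10 p of at least 3 and a log2 fold of at least 3, which is an 8-fold excess over input. Clusters were placed on the basic gene set of GENCODE 29 by their 5′ end on their own strand. The class order was small noncoding RNA exon, CDS, 5′ UTR, 3′ UTR, other noncoding exon, intron within 100 bases of a 5′ splice site, intron within 100 bases of a 3′ splice site, other intron, antisense and intergenic. Where genes overlap on a strand, a gene with an exon at that point came first, then a protein-coding gene, then the shorter gene. Intron numbers follow the longest transcript of a gene, coding transcripts first. Gene names are those of GENCODE 29.

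Feature classes and the spanning of splice sites were compared between enriched clusters and the clusters of the same list that were not enriched, with Fisher's exact test, two-sided, adjusted by Benjamini-Hochberg over all classes (or sites) and both replicates. A class counted as called when the adjusted p was below 0.05 in both replicates with the same direction. Log2 odds ratios had 0.5 added to each cell. Reproducible peaks were also compared with the clusters enriched in neither replicate. Intervals on shares are exact Clopper-Pearson intervals at 95% and cover counting error only. Clusters in a gene are not independent, adjacent clusters can be pieces of a single stretch of coverage, and the p-values describe these libraries. Whether the replicates came from separate cultures is not stated in the labels, so the spread between them may be technical.

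For 18 gene lists written before the data were examined, the share of genes with a reproducible peak, among genes with a cluster in each replicate, was set against 10000 random lists matched on the number of clusters per gene in 10 bins, with a two-sided permutation p adjusted over the lists with at least 5 such genes. The histone list was meant for replication-dependent genes but was taken by name and includes the replication-independent H1F0 and H1FX. The design called for 6-mers counted from 25 bases upstream to 50 bases downstream of cluster 5′ ends in introns. Genome sequence was not used here, so this ran only on windows wholly inside an exon of some transcript in the comprehensive gene set, such as a retained intron. These were 7021 of 102819 intronic clusters in replicate 1 and 8215 of 129870 in replicate 2. Distances to chromosome ends used the first base and the end of the last annotated gene on each chromosome.

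The rule for named genes was fixed at the same time as the lists. It takes the 25 genes whose strongest reproducible peak has the highest fold, the 10 genes with the most reproducible peaks, up to 4 members of each list with the highest fold or up to 2 with the most clusters where none has a peak, PRPF39 itself, and genes behind any count of 5 or fewer. Some members that the rule takes are not reported here. Alternatives changed the threshold, the overlap, the source of the reproducible set, the point that gives the class, the background, the splice-site window, the matching and the replicates used, and some were added after seeing the data. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and were tested on simulated data. Random relabelling of enriched clusters called 0 of 800 classes, a log2 odds ratio of 1 was recovered as 0.99 on average over 100 simulated sets, and 5 of 200 random gene lists had a permutation p below 0.05. The relabelling shuffled single clusters in each replicate separately, so it does not test the p-values under the dependence of clusters within genes. A 6-mer planted in simulated windows was called, and the 4 others called overlapped it.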

Results

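PRPF39 seCLIP clusters that stood out over input lay mainly in introns. A larger share of them than of other clusters lay in the first 100 bases after annotated 5′ splice sites. Relative to the other clusters, the excess was as large from 100 to 500 bases. Enriched clusters were scarce in coding exons, where an effect of mature mRNA in the input on the fold was not tested. A single gene, PTPRN2, held 509 of the 6785 reproducible peaks. U1 snRNA genes had few clusters and none that passed, and how well reads map to these genes was not tested. The data comprised 2 PRPF39 immunoprecipitates and 2 size-matched inputs from HepG2 cells, a human liver cancer line, and the study sought the RNA targets of PRPF39. Replicate 1 had 141377 clusters and replicate 2 had 172026, with median lengths of 55 and 52 bases. Depth per library is unknown.

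In replicate 1, 7830 clusters (5.54%, exact 95% interval 5.42 to 5.66%) were enriched, and in replicate 2, 9826 clusters (5.71%, 5.60 to 5.82%). Enriched clusters lay in 2258 genes in replicate 1 and in 2576 genes in replicate 2. The same places tended to pass in both libraries: 65.5% of the enriched clusters of replicate 1 (64.5 to 66.6%) overlapped an enriched cluster of replicate 2. Among the clusters of replicate 1 that overlapped any cluster of replicate 2, an enriched cluster was met by 74.3% of the enriched ones (73.2 to 75.3%) and by 5.44% of the others (5.25 to 5.64%). The log2 odds ratio of these shares was 5.65 ± 0.05 (SE), and the exact Fisher p was too small for double precision to hold. Across 66854 overlapping cluster pairs, the log2 fold had a Pearson r of 0.824 and a Spearman rho of 0.772, described over clusters, which are not independent replicates. The median absolute difference between the replicates was 0.64 on the log2 scale.

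**Figure D1:**
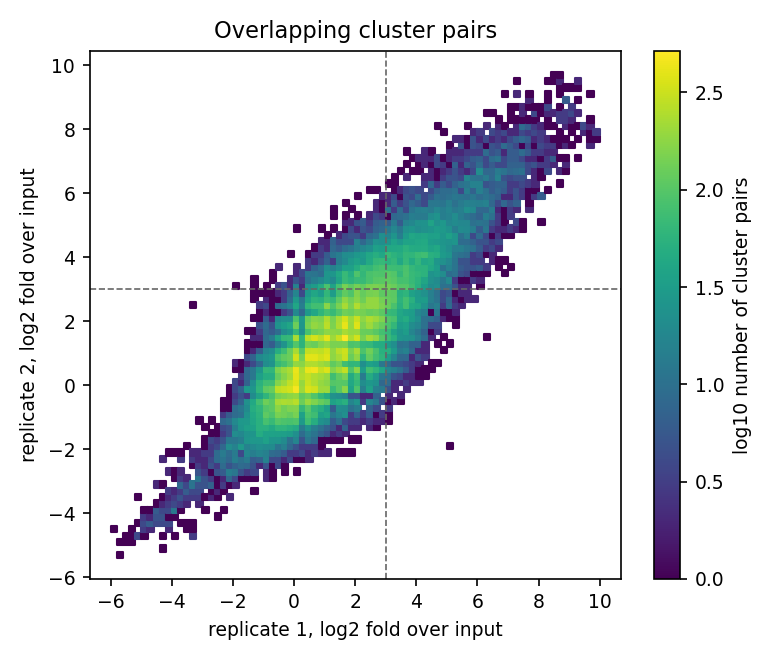
Log2 fold over input of overlapping cluster pairs, replicate 1 on the x axis and replicate 2 on the y axis, as squares of 0.2 log2 units coloured by the log10 number of pairs. Dashed lines mark the fold threshold of 3, and the 66854 pairs have a Pearson r of 0.824.

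The authors' table of both replicates held 6785 reproducible peaks in 1894 genes, of which 1772 were protein-coding and 35 were lincRNA genes. The median of the authors' log2 fold was 4.05, a 16.6-fold excess, and the median peak length was 82 bases. An enriched cluster of each replicate overlapped 80.7% of these peaks. Peaks were unevenly spread over genes, since 911 genes had 1 peak and 118 genes had at least 10. The 10 genes with the most peaks held 14.6% of them.

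PTPRN2, which encodes a receptor-type phosphatase of secretory granules, lies on chromosome 7 from 157539056 to 158587788 (GRCh38, minus strand). Its 509 reproducible peaks made up 7.50% of the total, and 507 of them were in introns away from splice sites. Intron 11 held 184 peaks, intron 2 held 104, intron 9 held 61 and intron 6 held 59. The strongest was in intron 6 at 158151081 to 158151090, with a log2 fold of 9.12 in the authors' table and of 9.63 in replicate 1 and 9.09 in replicate 2. The other genes with the most peaks were FTCD (70), ZFPM1 (68), RPH3AL (68), BDH1 (60), COL18A1 (55), the noncoding LINC02320 (43), TAF4 (41), F7 (39) and PQLC1 (37). FTCD encodes a liver enzyme of histidine breakdown, BDH1 a ketone body enzyme and F7 coagulation factor VII. In all of the 10 genes with the most peaks except LINC02320, the peaks lay within 3 Mb of a chromosome end. Every one of the 77 clusters in FTCD in replicate 1 and the 67 in replicate 2 was enriched. The reproducible peaks of FTCD lay between 46143216 and 46151816 and covered 2183 bases of a gene of 19306 bases. Adjacent peaks can be pieces of a single stretch of coverage, and merging peaks within 100 bases left 3920 loci.

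**Figure D2:**
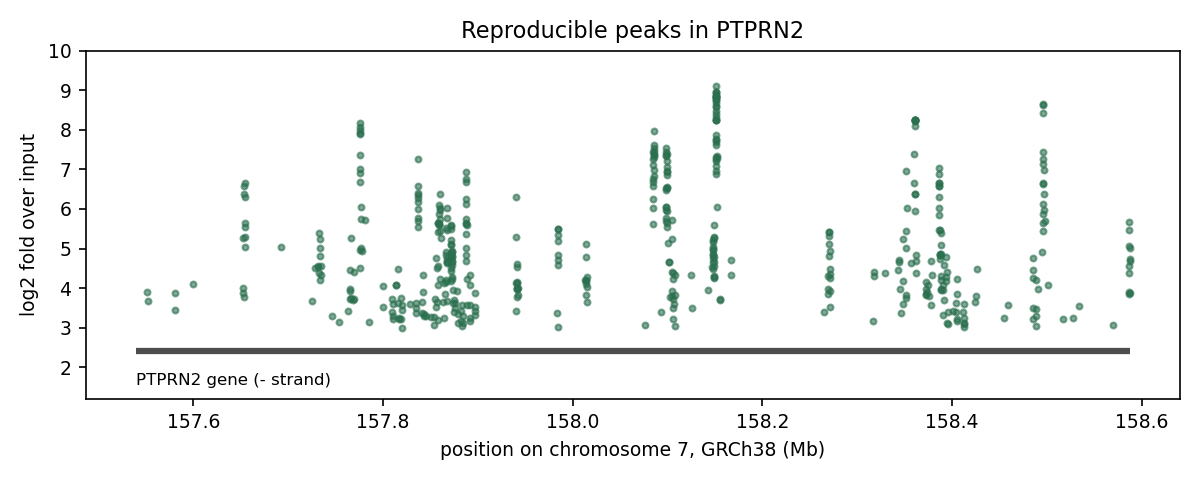
Reproducible peaks in PTPRN2, with position on chromosome 7 in Mb on the x axis and the authors' log2 fold over input on the y axis, each point a peak and the bar the gene. The 509 peaks form separate groups along the gene, with the highest at 9.12.

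The highest folds belonged to peaks in introns. TNKS, which encodes the poly(ADP-ribose) polymerase tankyrase, led with a log2 fold of 9.51 in the authors' table at chromosome 8, 9772132 to 9772194, in intron 26, and its replicate clusters had 9.12 ± 0.11 (SD, n = 2). SERINC2 followed with 9.24 (intron 9, chromosome 1, 31431959 to 31431976; replicates 9.36 ± 0.16, SD, n = 2). FTCD reached 9.20 in intron 10, and its replicates were farther apart (9.06 ± 0.78, SD, n = 2). PTPRN2 came next with 9.12. SLC12A7, a potassium-chloride cotransporter gene, reached 8.91 in intron 1, and NME4 8.51 in intron 1. LINC02320 had 8.47, SARDH 8.39, MINK1 8.33, BDH1 8.21, ZNF516 8.16, B4GALNT4 8.05 and F7 8.01. ADARB1, which encodes an RNA-editing adenosine deaminase, was the exception among the 25 highest genes with a peak in a 3′ UTR (8.21, chromosome 21, 45224538 to 45224550). FOXRED1 (8.06, intron 8, 82 bases after a 5′ splice site) and the DNA ligase gene LIG4 (7.67, intron 1, 69 bases after) were the 2 whose strongest peak lay within 100 bases of such a site. The remaining genes were ULK1, RAB17, RPH3AL, EIPR1, DTX2P1, ZFPM1, PERM1, FOXK2 and ST3GAL3, and over all 25 the fold ran from 7.41 to 9.51. In 22 of the 25 the strongest peak was in an intron away from splice sites, a class that held 73.6% of all reproducible peaks. In 13 of the 25 the strongest peak lay within 3 Mb of a chromosome end, as did 43.6% of all reproducible peaks.

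The comparison of annotation classes asked where in genes enriched clusters fell relative to other clusters of the same library. Introns within 100 bases downstream of a 5′ splice site held 12.8% of enriched clusters in replicate 1 (12 to 13.5%) against 5.04% of the others, and 13.6% (12.9 to 14.3%) against 5.2% in replicate 2. The log2 odds ratios were 1.46 ± 0.05 and 1.52 ± 0.05 (SE), with exact Fisher adjusted p of 9.31e-142 and 4.58e-201. Coding sequence was scarce, with 1.90% of enriched clusters against 14.9% of the others in replicate 1 and 1.93% against 14% in replicate 2. The log2 odds ratios for CDS were -3.17 ± 0.12 and -3.04 ± 0.11 (SE). 3′ UTRs were also under-represented (2.69% against 8.05%, and 2.61% against 6.45%; exact Fisher adjusted p = 1.32e-84 and 3.61e-65). Enrichment is relative to input, and whether mature mRNA in the input lowers the fold in these exons was not tested. The scarcity therefore does not show that PRPF39 avoids them. 5′ UTRs held 4.69% against 3.16% in replicate 1 and 4.6% against 2.67% in replicate 2 (exact Fisher adjusted p = 4.58e-12 and 4.55e-25), a call lost at the stricter threshold (mean log2 odds ratio 0.23).

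The remaining introns held 73.7% of enriched clusters in replicate 1 against 60.7% of the others, and 73.4% against 63.4% in replicate 2 (exact Fisher adjusted p = 3.18e-121 and 5.24e-92). This call was lost outside 5 Mb of chromosome ends, where the mean log2 odds ratio was 0.095, and with a splice-site window of 300 bases (0.074). Introns within 100 bases upstream of a 3′ splice site held 2.53% against 5.99% and 2.49% against 6.01% (exact Fisher adjusted p = 4.09e-45 and 4.17e-58). When the cluster midpoint gave the class in place of the 5′ end, that direction turned to a mean log2 odds ratio of 0.12. Among the 6785 reproducible peaks, 938 (13.8%) were near a 5′ splice site, against 4.93% of clusters enriched in neither replicate (log2 odds ratio 1.63 ± 0.05, SE).

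**Figure D3:**
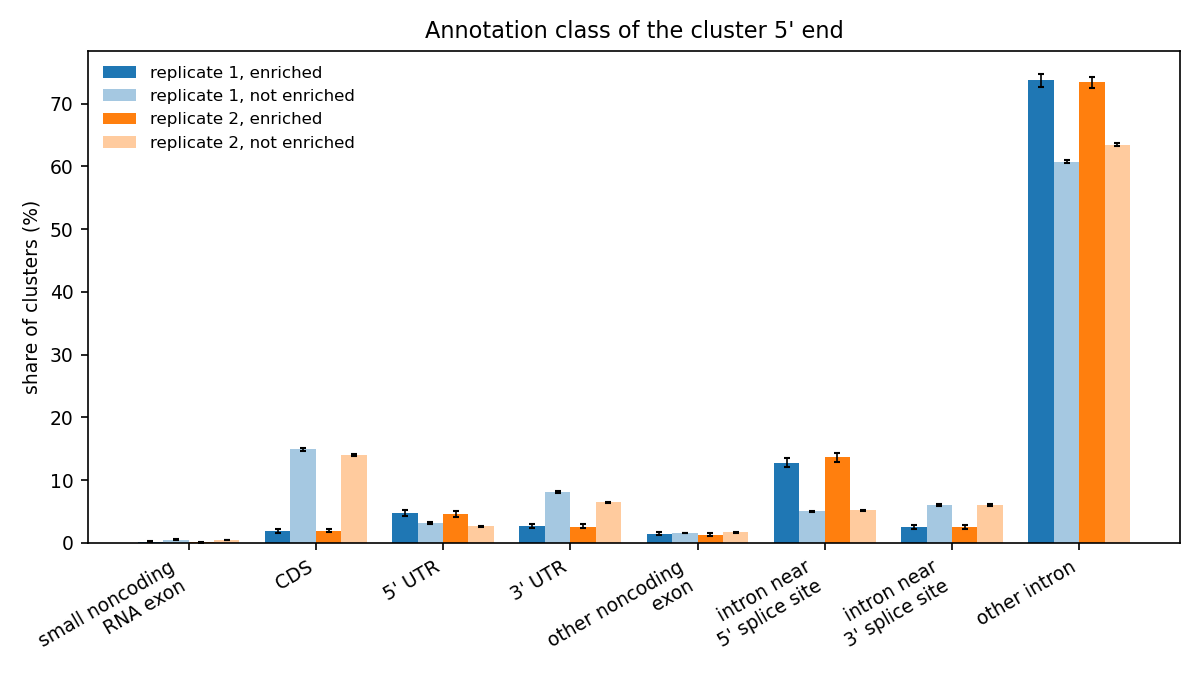
Share of clusters (y axis, %) in 8 annotation classes (x axis) for enriched and other clusters of each replicate, with exact 95% intervals as error bars. Near 5′ splice sites the enriched bars stand at 12.8 and 13.6% and the others at 5.04 and 5.2%.

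Around 5′ splice sites, the 5′ ends of enriched clusters gathered in the intron. The fullest 10-base bin was 30 to 40 bases downstream in replicate 1, with 2.36% of enriched clusters and 0.796% of the others, and 20 to 30 bases in replicate 2, with 2.4% and 0.734%. The 100 bases upstream, mainly exon, held 2.11% of enriched clusters against 9.92% of the others in replicate 1 and 2.0% against 9.51% in replicate 2. Relative to the others, the excess was as large farther in: the enriched share was 2.39 and 2.51 times that of the others within 100 bases downstream and 2.44 and 2.54 times from 100 to 500 bases.

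**Figure D4:**
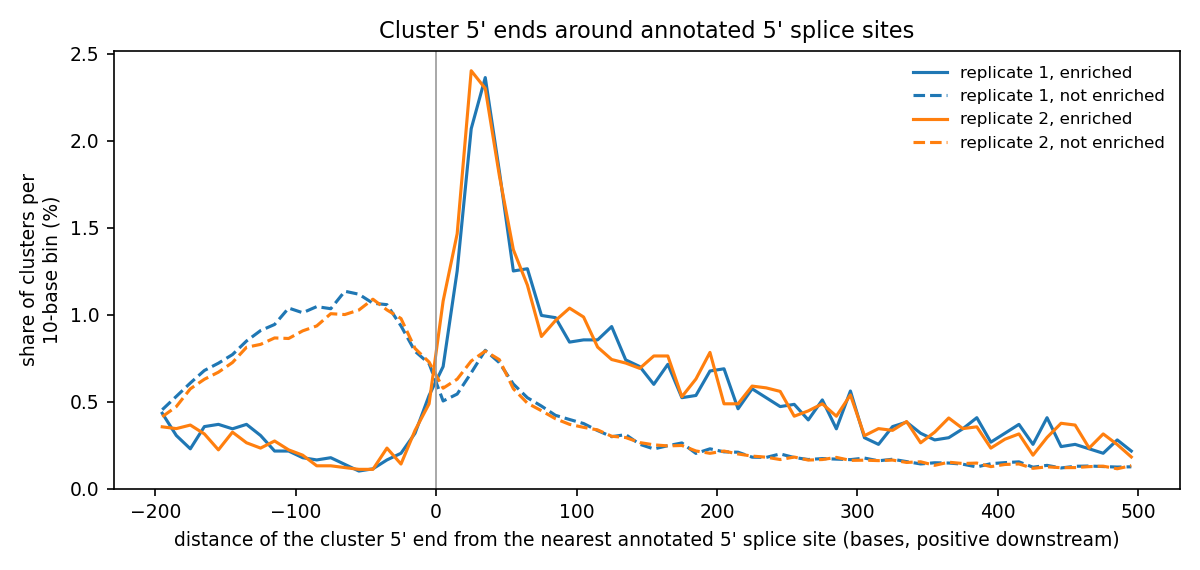
Share of cluster 5′ ends per 10-base bin (y axis, %) by distance from the nearest annotated 5′ splice site in bases (x axis, positive downstream). Solid lines for enriched clusters rise to 2.36 and 2.4% within the first 40 bases of the intron, and dashed lines show the other clusters.

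Fewer enriched clusters reached across a splice site. A 5′ splice site was spanned by 2.18% of enriched clusters against 3.43% of the others in replicate 1 and by 2.0% against 3.65% in replicate 2 (exact Fisher adjusted p = 3.51e-10 and 1.58e-19). A 3′ splice site was spanned by 4.43% against 6.37% and by 4.41% against 5.92% (exact Fisher adjusted p = 1.54e-12 and 1.64e-10). With 1 cluster per gene the 5′ site call was lost (mean log2 odds ratio -0.14) and the 3′ site direction reversed (0.43), and outside 5 Mb of chromosome ends the values were -0.33 and 0.15.

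Few clusters in small structured RNAs passed the threshold. The U1 snRNA genes had 3 clusters in replicate 1 and 6 in replicate 2, none enriched, with median log2 folds of 2.14 and 2.63 against 1.1 and 0.83 over all clusters. RNU1-2 reached 2.14 and 3.42, RNU1-4 0.73 and 3.42, and RNVU1-14 2.46 and 1.83. RNU1-2 and RNU1-4 passed the fold threshold in replicate 2 with a −log10 p of 2.39, below the one required. Their clusters there share the same fold, and those of RNU1-2 are adjacent pieces, so the medians rest on few distinct values. The replicate 2 clusters include loci named as pseudogenes, RNU1-13P (-0.75) and RNU1-67P (1.83). How well reads map to these genes was not tested, so these few clusters leave contact with U1 snRNA open. Clusters in snoRNAs lay below input, with a median log2 fold of -2.41 over 333 clusters in replicate 1 and -2.26 over 403 in replicate 2, and 0 were enriched. Clusters on the mitochondrial genome had medians of 0.24 and -0.07, also with 0 enriched, and MT-RNR2 reached 0.59 and 0.46. Some loci passed in replicate 1 alone: SCARNA2 had 4 enriched clusters there (highest log2 fold 3.82, against 0.47 in replicate 2) and RNU2-4P had 1 (4.14 against 0.29). In replicate 2 alone, RF01955, which lies within the span of NEAT1, passed with 3.01 against 2.97, and a cluster assigned to TRAPPC4 with 3.08. The RF01955 folds lie just on either side of the threshold, so the replicates hardly differ there. The minor spliceosomal RNAs RNU12 (-0.35 and 0.14) and RNU4ATAC (-1.04 and -0.20) stayed near or below input at their highest. The 4 reproducible peaks in small noncoding RNAs were 3 in VTRNA1-1, a vault RNA (4.08 in the authors' table, replicates 4.08 ± 0.02, SD, n = 2), and 1 in SCARNA17 (3.11, replicates 3.03 ± 0.03, SD, n = 2). The replicate 2 cluster behind the SCARNA17 peak begins upstream of the gene, so it is not counted among the clusters in scaRNAs.

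The gene for PRPF39 itself, on chromosome 14, had 2 reproducible peaks. The first was in intron 3 at 45096526 to 45096602, with a log2 fold of 5.10 in the authors' table and of 3.82 and 6.08 in the replicates. The second was in intron 8 near a 5′ splice site at 45109826 to 45109913, with 3.37 in the table and 3.31 and 3.42 in the replicates.

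Gene lists asked whether groups of genes carried reproducible peaks more often than genes with as many clusters. Of 11222 genes with a cluster in each replicate, 1890 (16.8%) had a peak. Of the 15 lists with enough genes, 0 passed the permutation test after adjustment and 3 had an unadjusted p below 0.05. Among hnRNP proteins, which package nascent RNA, 15 of 28 genes (53.6%) had a peak against 30.5% in matched lists (permutation p = 0.0148, adjusted 0.111). HNRNPA2B1 (6.28, intron 2, 34 bases after a 5′ splice site), SYNCRIP (5.88), HNRNPU (5.14) and HNRNPK (4.97) had the highest folds in the authors' table. Translation factors had peaks in 14 of 37 genes (37.8% against 20.01%, permutation p = 0.0124, adjusted 0.111), led by EIF6 (4.35), EIF3G (4.27), EIF5A (4.24) and PABPC1 (4.17). Their difference of 17.8 percentage points fell to 5.22 without replicate 1 and to 2.35 at the stricter threshold. snoRNA and scaRNA genes had a peak in 1 of 209 (0.478% against 2.99%, permutation p = 0.0222, adjusted 0.111).

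In the main test the other splicing lists lay close to their matched lists. U1 snRNP proteins and associated factors had peaks in 6 of 26 genes (23.1% against 20.2%), among them PRPF39 itself (5.10), TAF15 (3.96) and TIAL1 (3.64). SR proteins and related factors had peaks in 8 of 27 (29.6% against 25.3%), with CLK2 (4.22), SRRM2 (4.22), SRSF5 (4.0) and SRSF6 (3.91). Over the alternatives their difference ran from -3.93 percentage points at the stricter threshold to 20.4 with overlapping enriched clusters at the looser one. The list was called in none of them. For the SRSF5 peak the replicate clusters with the largest overlap had 3.19 and 1.16. Those of SF3B1 in the spliceosome list had 1.31 and 4.08, and those of RPS6 among ribosomal proteins 1.08 and 3.71. The authors' folds of these peaks (4.0, 4.20 and 3.72) lay above both replicate values in each case. These clusters therefore need not be the ones behind the peaks, and their spread is not evidence of uneven peaks. The U2, U4/U6.U5 and catalytic spliceosome proteins had peaks in 8 of 43 (18.6% against 17.5%), with SART1 (6.84), SF3B1 (4.20), U2AF2 (4.11) and DHX8 (4.09). The list written for nuclear long noncoding RNAs had peaks in 4 of 16 (25.0% against 23.9%), namely NORAD (4.29), NEAT1 (3.73), TUG1 (3.24) and KCNQ1OT1 (3.18). Where these RNAs lie in the cell was not examined.

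Coagulation and complement proteins had peaks in 8 of 28 genes (28.6% against 21.1%), with F7 (8.01), C3 (7.0), SERPINF2 (4.94) and FGG (4.45). Hepatocyte secreted proteins had peaks in 6 of 31 (19.4% against 22.3%), with ITIH2 (4.99), APOB (4.41), SERPINF1 (4.37) and RBP4 (3.45). Cholesterol and fatty acid synthesis genes had peaks in 9 of 31 (29% against 30.6%), with SREBF1 (5.78), ACACA (5.18) and TM7SF2 (4.85). Cytosolic ribosomal proteins had peaks in 7 of 78 (8.97% against 14.1%), and RPS21 (4.20), RPS7 (3.8), RPS6 (3.72) and RPS24 (3.63) all had their strongest peak within 100 bases after a 5′ splice site. No gene had a peak among 23 mitochondrial, 17 histone and 12 spliceosomal snRNA genes other than U1. The replication-independent linker histone genes H1F0 and H1FX reached 2.7 and 2.18, and 1.6 and 1.25. Other small structured RNA genes had a peak in 1 of 12. The lists of U1 snRNA (3 genes with clusters), neuronal (2) and blood cell genes (2) were too short to test, and SYP, SLC17A7, LYZ and ITGA2B had no enriched cluster.

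**Figure D5:**
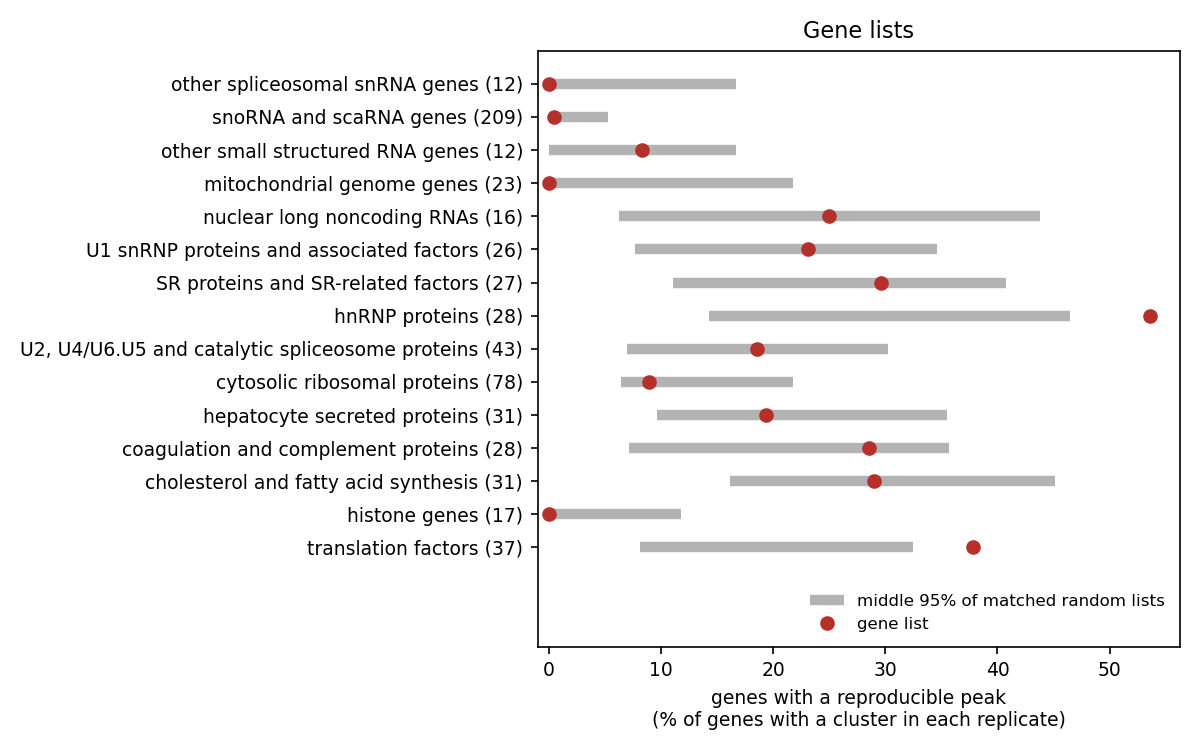
Share of genes with a reproducible peak (x axis, %, among genes with a cluster in each replicate, number in brackets) for the 15 tested lists (y axis). Points are the lists and grey bars the middle 95% of matched random lists, with hnRNP proteins at 53.6% and translation factors at 37.8% to the right of their bars.

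G-rich and GC-rich 6-mers were more frequent in the intronic windows of enriched clusters for which sequence could be read. Of all 6-mers, 78 were called higher and 1, CTCTCT, lower in both replicates. GCGGGG was present in 20.4% of 626 enriched windows and 6.48% of the others in replicate 2, and in 20.7% of 497 and 5.99% in replicate 1 (exact Fisher p = 1.2e-27 and 1.87e-25). GGGAGG was present in 31.9% and 17.9% in replicate 2 and in 31.2% and 15.7% in replicate 1 (exact Fisher p = 8.48e-16 and 1.97e-16). None of the 6 donor-like 6-mers was called, and none had an unadjusted p below 0.05 in both replicates. GGTGAG came closest, in 8.25% and 5.38% of windows in replicate 1 (exact Fisher p = 0.0109) and in 8.15% and 6.15% in replicate 2 (exact Fisher p = 0.0591). Each window began 25 bases upstream of the cluster 5′ end. A cluster that started farther into an intron than this left out the 5′ splice site. The fullest bin of enriched clusters lay 30 to 40 bases downstream in replicate 1 and 20 to 30 bases in replicate 2. The lack of a donor-like call therefore cannot decide whether enriched clusters lie near such sequence. Windows with sequence made up 7.13% of the enriched intronic clusters in replicate 1 and 7.12% in replicate 2, and none lay in PTPRN2. With 1 cluster per gene 27 6-mers were called higher, and outside 5 Mb of chromosome ends 43, and the lower call was lost in both and at the stricter threshold.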

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

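The choices involving PTPRN2, chromosome ends, merged peaks, the comprehensive annotation, 6-mers with 1 cluster per gene and the own intersection at another overlap or threshold were added after seeing the data. No paired analysis was possible because each immunoprecipitate is already set against its own input in the deposited folds and the inputs had no values of their own. The looser threshold and another overlap could not be applied to the authors' table, which holds no peak below 3, so an own intersection of enriched clusters stood in. Depth is unknown and limits what low folds can show.

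The 5′ splice site, CDS and 3′ UTR classes kept their direction and call under every alternative run, with mean log2 odds ratios from 0.88 to 4.0 for the first. The cause of the changes below was not tested. At the stricter threshold there were 3260 and 4148 enriched clusters, 3216 reproducible peaks, 832 genes with a peak, 14 6-mers called higher and 0 lower, and the log2 odds ratios were -2.25 for small noncoding RNA exons (call lost), 0.23 for 5′ UTRs (lost) and -0.61 for other noncoding exons (gained). At the looser one there were 16174 and 19172 enriched clusters, 206 6-mers higher and 82 lower, and -0.020 for spanning a 3′ splice site (lost). The looser own intersection gave 13208 peaks, 2995 genes and 3 called lists, and merging peaks left 3920. With 1 cluster per gene other noncoding exons stood at -1.68 (gained), spanning at -0.14 for 5′ (lost) and 0.43 for 3′ sites (reversed), and 27 6-mers were higher and 0 lower. Outside 5 Mb of the ends the values were -0.82 for small noncoding RNA exons (lost), 0.22 for other noncoding exons (reversed), 0.095 for other introns (lost), -0.33 and 0.15 for spanning 5′ (lost) and 3′ sites (reversed), with 43 6-mers higher and 0 lower. The comprehensive annotation turned other noncoding exons to 0.27 (called), the midpoint turned introns near 3′ splice sites to 0.12, a 300-base window left other introns at 0.074 (lost), and a background at or below input left 3′ site spanning at -0.076 (lost). Leaving out a replicate gave -0.42 to -0.063 for other noncoding exons (gained without replicate 1), 0 to 1 called lists (snoRNA and scaRNA genes without replicate 1), 95 to 157 6-mers higher and 14 to 40 lower.

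Without matching, 3 lists were called. Lists not called in the main test changed the sign of their difference from matched lists (percentage points) as follows. At the stricter threshold it was -4.92 for nuclear long noncoding RNAs, -5.08 for U1 snRNP proteins, -3.93 for SR proteins and -0.36 for U2 and other spliceosome proteins, and with the own intersection -6.89, -0.88, -1.96 and -0.041. The looser own intersection gave -0.77 for other small structured RNAs, -2.66 for U2 and other spliceosome proteins, -0.72 for coagulation and 25.5 for cholesterol genes, the last called. Without matching it was -8.32 for other small structured RNAs, 2.49 for hepatocyte and 12.2 for cholesterol genes, and with 3 clusters per gene -1.05 for U2 and other spliceosome proteins. Leaving out a replicate gave -6.30 to 3.77 for other snRNAs, -2.89 to 12.3 for nuclear long noncoding RNAs, -3.05 to -0.12 for U2 and other spliceosome proteins, -3.73 to 2.76 for hepatocyte and -3.90 to 16.0 for cholesterol genes.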

Other observations

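The tests of mature mRNA in the input, of blood cell RNA and of the number of clusters were chosen after the result was seen, and each pattern below was found and tested on the same data. The design gives no groups that would test a biological explanation.

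Reproducible peaks lay close to chromosome ends: 43.6% (42.4 to 44.8%) were within 3 Mb of an end, against 11.8% of clusters that were not enriched, and by gene the contrast was smaller, with a peak in 34.1% of genes there and 14.6% of genes farther away. Outside PTPRN2 the share was 39.0%, and with peaks within 100 bases merged it was 39.6%, so neither this gene nor split coverage accounts for the whole pattern. Among peaks with a −log10 p of at least 20 the share was 57.8%, which argues against few reads behind the folds. Donor-like 6-mers away from annotated 5′ splice sites, in 340 and 417 enriched windows with none in PTPRN2, gave a mean log2 odds ratio of 0.35 (exact Fisher p = 0.0124 and 0.750), and within 3 Mb of an end 1.07 and 0.11 (exact Fisher p = 0.00616 and 0.794). This leaves that explanation open, and GC content, tandem repeats and mappability were not tested.

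The nearness of enriched intronic clusters to 5′ splice sites persisted in each of the tests below, all of them on the first 100 bases. Among intronic clusters alone, the mean log2 odds ratio was 1.2. Introns were assigned by the cluster 5′ end, so clusters that run into the next exon stayed in. Near 3′ splice sites the log2 odds ratios among intronic clusters were -1.64 and -1.61. This restriction therefore cannot set aside mature mRNA in the input. Stratified by gene, the mean log2 odds ratio for 5′ splice sites was 1.33, which argues against genes with short introns as the whole cause. Outside 5 Mb of chromosome ends it was 1.89. What causes the nearness was not tested.

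MicroRNA loci passed in replicate 1 without passing in replicate 2 at 5 genes, MIR451A (log2 fold 6.67), MIR20A (5.43), MIR17 (5.10), MIR19B2 (5.10) and MIR142 (4.23). MIR638 (4.16) and MIR3940 (4.0) passed in replicate 2 alone, and 0 passed in both. The counts of 5 of 70 against 2 of 68 loci did not differ clearly (exact Fisher p = 0.441). That test treats the loci of the 2 replicates as independent, though the same genes can be in both. It compares counts only and does not bear on single loci. MIR451A and MIR142 are typical of blood cells, but 0 of the 24 genes of the blood cell list had an enriched exonic cluster in replicate 1. Only 2 of them had any cluster there, HBA1, HBA2 and HBB not among them, so this test could detect little. Replicate 1 had 76 clusters in microRNA genes against 70 and fewer in all, but the passing loci themselves are among the 76, so this count does not explain them and the cause stays open.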
